A study of Mus musculus with 6 samples.

How the data were processed

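Poly(A)-selected RNA of BV2 cells was sequenced on an Illumina NovaSeq instrument after NEBNext Ultra library preparation, in 3 libraries of cells given vehicle and 3 of cells given LPS. The kit is not stated to mark the strand. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2 were used, and the notes used here give these tools no order or role. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The deposited values, made by the authors, are expected counts, that is, estimated counts per gene for each library. All were whole numbers already, so rounding changed nothing. Their low values piled up at a spacing of 3.64 to 3.86 counts per library, so a value cannot be taken as a number of reads. Every sample column of the table was mapped to its sample by name, and 0 columns were left unmapped.

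Gene names, biotypes and transcript lengths were taken from a mouse gene annotation by Ensembl identifier. The length of a gene was that of its longest annotated transcript. Reads shared between near-identical copies (Bcl2a1, H2, Gbp, Oas1, Naip and ribosomal protein genes with their pseudogenes) or between overlapping genes on either strand can be assigned to the wrong gene, and such values are uncertain.

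Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the quasi-likelihood F-test, two-sided, with robust dispersion estimates compared LPS with Vehicle. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The SE of a log2 fold change is its size over the square root of F. CPM were scaled by TMM, and log2 CPM used a prior count of 2. Lists of genes were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01 and, beside it, with an estimated correlation, and were tested on their own with fry. Medians of lists are of edgeR's fitted log2 fold changes, while those given with the alternatives in the sensitivity analysis are of differences in log2 CPM. A list needed at least 5 tested genes, and p-values were adjusted over the lists. DESeq2 1.42.0 was used as an alternative, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

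The 37 gene lists, the comparison and the rule for naming genes were fixed before the data were examined. Genes named are, first, the 10 largest rises and the 10 largest falls among called genes with a symbol that is not a predicted name, groups that do not overlap and a mean of at least 5 CPM. Next come up to 4 called members of each list with the largest changes, at least 1 each way where members went both ways, and up to 2 called members of the lists for other cell types and library quality. Tlr4, Cd14, Nos2, Tnf, Il1b, Il6, P2ry12 and Tmem119 were named whatever their result. Only part of these is printed, and results for some genes are not reported.

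Library totals ran from 45969690 to 59023474 estimated counts, with 18984 to 20615 genes above 0. For genes at 0 in a whole group the floor was 3 steps, 11.3 counts per library (0.218 CPM as the mean of the Vehicle libraries). It covers counting error only, as reads without molecular identifiers are not independent molecules.

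The procedure was tested on simulated data. With whole counts, 8.96%, 45.5% and 80.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 9 of 98 calls were false (9.18%). With counts in steps the shares were 14.9%, 65.7% and 83.3%, and 10 of 119 calls were false (8.40%). These shares of false calls exceed the nominal 5%, and each rests on a single draw. Each draw changed only 67, 67 and 66 genes by 1.5-fold, 2-fold and 4-fold, with 15599 or 15605 genes tested. In the data 23.6% of genes were called, and the adjusted cut-off is stricter where fewer genes change. The recovered shares therefore do not give the power in these data.

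Alternatives covered other scalings (the size factors of DESeq2, upper quartile and total counts only), no filter and a stricter filter on low counts, the DESeq2 Wald test, limma voom, edgeR's test as it was before version 4, a block for the replicate number, the estimated correlation, and leaving out each library. Division of the values by their step was added after seeing the data.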

Results

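RNA was measured by sequencing of poly(A)-selected transcripts in BV2, an immortalised mouse microglial cell line, after treatment with lipopolysaccharide (LPS) or with vehicle. LPS is a component of the outer membrane of Gram-negative bacteria that is sensed by the receptor complex of Tlr4, Cd14 and Ly96. Each group held 3 libraries, and the labels gave neither a dose nor a time of treatment. Estimated counts were listed for 55401 genes, and each library totalled between 45969690 (Vehicle 3) and 59023474 (Vehicle 1) of them. The low values piled up at a spacing of 3.75 counts, for a reason not tested here, so a count cannot be taken as a read. The study asked which genes regulate the inflammatory activation of microglia, and the comparison shows which transcripts differed with LPS. Values after ± on a log2 fold change are standard errors (SE) from edgeR, with 3 libraries per group throughout. The labels did not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

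The libraries separated by treatment on the first principal component of log2 CPM (counts scaled to a common library size), which held 43.6% of the variance. The second component, with 19.3%, spread the LPS libraries from LPS 1 at 62.8 to LPS 3 at -66.3, while the Vehicle libraries lay between -0.90 and 16.5. Across genes, Pearson's r of log2 CPM was 0.967 to 0.970 between Vehicle libraries, 0.951 to 0.962 between LPS libraries and 0.929 to 0.944 between the groups. These correlations are across genes, which are not independent replicates. The 10 most abundant genes took 5.52% to 7.15% of the counts of a library.

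**Figure D1:**
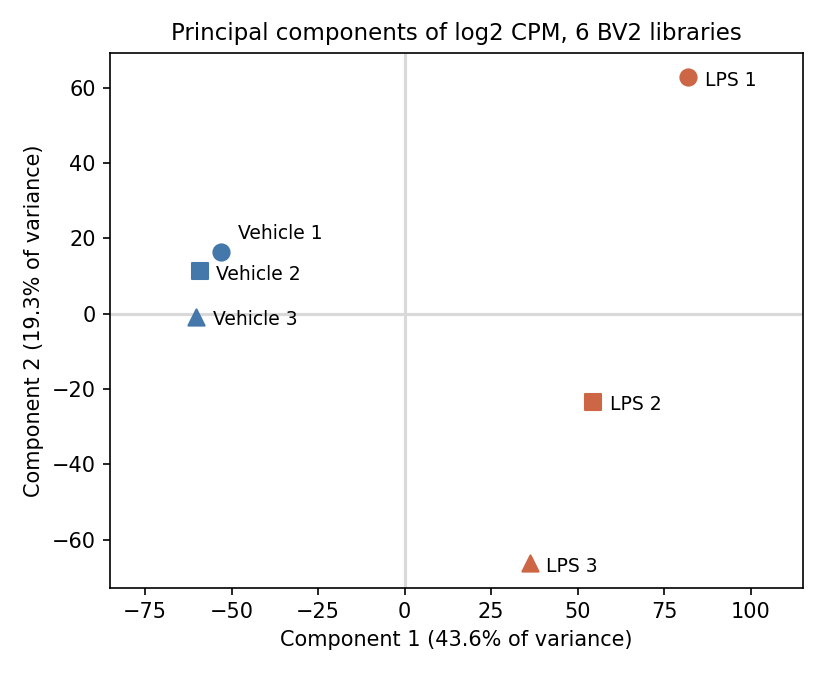
Scores of the 6 libraries on the principal components 1 and 2 of log2 CPM over the tested genes, with the share of variance on each axis; blue marks Vehicle, orange marks LPS, and the symbol marks the replicate number. Vehicle libraries sit between -60.3 and -52.9 on component 1 and LPS libraries between 36.1 and 82.0.

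Cytokine genes were among the 10 largest rises with LPS. Csf3 (ENSMUSG00000038067), a growth factor for granulocytes, rose from 1.97 ± 0.96 to 938 ± 297 CPM (SD, n = 3), a fitted 494-fold rise. Lcn2 (ENSMUSG00000026822), an iron-scavenging defence protein, rose 370-fold, Il6 (ENSMUSG00000025746) 251-fold, Il1b (ENSMUSG00000027398) 240-fold and the chemokine gene Cxcl2 (ENSMUSG00000058427) 218-fold. Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, rose from 2.51 ± 0.32 to 513 ± 56.6 CPM (SD, n = 3). Il1a, Serpinb2, Ntng2 and Saa3 completed the 10 largest rises, with log2 fold changes of 7.35 ± 0.22, 7.20 ± 0.36, 6.58 ± 0.38 and 6.37 ± 0.32.

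The falls were smaller. Gpr183 (ENSMUSG00000051212), a receptor for oxysterols that guides immune cells, fell from 28.3 ± 1.22 to 2.98 ± 1.24 CPM (SD, n = 3), a log2 fold change of -3.26 ± 0.23. Dmpk (ENSMUSG00000030409), a protein kinase, and Hdac9, a histone deacetylase, followed with -3.04 ± 0.25 and -2.50 ± 0.28. Frmd4b, Igfbp4, Abca9, Bola1, Abcd2, Efr3b and Ankle1 had log2 fold changes between -2.41 and -2.05. These 20 genes were chosen among those with groups that do not overlap, and their largest adjusted p from edgeR's quasi-likelihood test was 0.00423, for Bola1.

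Of 16371 genes tested, 3864 (23.6%) changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these 2082 were higher and 1782 lower with LPS. With total counts in place of TMM scaling, 42.2% of the changed genes were higher, against 53.9% with TMM, and the median log2 fold change of all tested genes was -0.10 in place of -0.02. A change of at least 2-fold was found for 1280 genes, 731 higher and 549 lower, and for 732 genes after a stricter filter on low counts. In 6685 genes (40.8% of those tested, where chance gives 10%) the libraries of both groups did not overlap, and 3854 of the changed genes were among them. Leaving out Vehicle 2 left 2344 changed genes, 1291 higher and 1053 lower. The number of genes lower with LPS was 1150 without Vehicle 1 and 1153 without LPS 2.

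Genes for cytokines and chemokines rose together. Of 19 tested members of the list of proinflammatory cytokines, 12 rose, none fell and 7 did not pass the test. Besides Csf3 and Il6, Tnf (ENSMUSG00000024401) rose from 98.3 ± 6.13 to 1034 ± 87.3 CPM (SD, n = 3), a log2 fold change of 3.40 ± 0.10 (edgeR adjusted p = 6.35e-07). Il12b, a subunit of interleukins 12 and 23, and Tnfsf15 had no counts in any Vehicle library. Against a floor of 11.3 counts per library (3 steps) they were at least 25.2-fold and at least 3.05-fold higher. Of 15 chemokine genes, 11 rose and 2 fell. Cxcl2 rose as given above, and Ccl22, a ligand of Ccr4, rose from 0.19 ± 0.17 to 5.53 ± 1.95 CPM (SD, n = 3). Cxcl3, at 0 in every Vehicle library, was at least 13.7-fold higher, and Cxcl14 fell with a log2 fold change of -1.04 ± 0.15. A single chemokine gene fell without Vehicle 2, Vehicle 3 or LPS 2.

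The median log2 fold change was 3.22 for the cytokine list and 2.71 for the chemokine list, and 2.08 and 2.71 with the genes at 0 in Vehicle set to their bound. Adjusted over the list alone, 14 cytokine genes rose, and 11 chemokine genes rose and 2 fell. The set test camera called both lists higher, with an adjusted p = 3.02e-10 for cytokines and 1.95e-06 for chemokines. With an estimated correlation between genes the camera adjusted p = 0.0809 for both.

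The LPS receptor and its adaptors moved in different directions. Cd14 (ENSMUSG00000051439), the co-receptor that hands LPS to Tlr4, rose from 286 ± 12.2 to 1024 ± 282 CPM (SD, n = 3), a log2 fold change of 1.84 ± 0.20 (edgeR adjusted p = 0.000731). Irak3, an inhibitor of the pathway, and Irak2, one of its kinases, rose with log2 fold changes of 2.01 ± 0.25 and 1.46 ± 0.13. Tlr4 (ENSMUSG00000039005) did not pass the test, with a log2 fold change of -2.53 ± 0.87 (edgeR adjusted p = 0.0975). Its CPM values were 31.3, 3.31 and 35.7 in Vehicle 1, 2 and 3, and 4.85, 4.04 and 3.37 in LPS 1, 2 and 3. Without Vehicle 2 the log2 fold change was -3.04 ± 0.19 and the edgeR adjusted p = 0.000267, while over all alternatives the adjusted p ran from 0.000267 to 0.33. DESeq2 called Tlr4 lower with all libraries, with an adjusted p = 0.0190. Of 22 tested members of this list 7 rose and 2 fell, the same numbers as adjusted over the list alone, the median was 0.01, and camera did not call the list (adjusted p = 0.224). Map3k7, the kinase also called TAK1, had -0.34 ± 0.11 (edgeR adjusted p = 0.0483) and lost the call without Vehicle 1, Vehicle 2, LPS 1 or LPS 2, with values up to 0.166. The number of falls was 0 without Vehicle 1 or LPS 1, and 1 without Vehicle 2, Vehicle 3 or LPS 2.

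NF-kB subunits and their feedback targets rose. Of 24 tested members 17 rose and none fell, with a median log2 fold change of 1.34. Traf1, a signalling adaptor of TNF receptors, rose from 4.25 ± 0.07 to 103 ± 16.7 CPM (SD, n = 3), a log2 fold change of 4.60 ± 0.16. Nfkbiz, an atypical inhibitor protein that also activates secondary response genes, and Zc3h12a, an RNase that degrades cytokine transcripts, had 3.73 ± 0.10 and 3.18 ± 0.11. Bcl3 had 2.38 ± 0.17. When adjusted over the list alone, 20 rose. Camera called the list (adjusted p = 1.73e-13, and adjusted p = 0.0798 with an estimated correlation). Both Bcl2a1 genes in this list belong to a family of near-identical copies, between which reads can be split.

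Genes that restrain cytokine and MAP kinase signalling rose as well. Of 20 tested members 12 rose and 3 fell, and the median log2 fold change was 1.04. The SOCS family genes Cish and Socs3 had log2 fold changes of 4.49 ± 0.20 and 3.40 ± 0.13, and the MAP kinase phosphatase gene Dusp10 had 2.47 ± 0.38. Zfp36l2, which encodes an RNA-binding protein, fell with -1.03 ± 0.11. Adjusted over the list alone 16 rose and 3 fell, and camera gave an adjusted p = 1.16e-05, and an adjusted p = 0.0796 with an estimated correlation.

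Among genes of the type I interferon response, 18 of 36 tested members rose and 1 fell, with a median log2 fold change of 0.45. Rsad2, which encodes the antiviral protein viperin, rose from 357 ± 18.0 to 976 ± 39.0 CPM (SD, n = 3), a log2 fold change of 1.45 ± 0.08. Slfn5 and Isg15 had 1.63 ± 0.19 and 1.33 ± 0.17. Mx1 was lower, with -1.21 ± 0.28, and lost its call without Vehicle 1, Vehicle 2 or LPS 2 (edgeR adjusted p up to 0.0665, against 0.0163 with all libraries). Without LPS 3, 3 members fell. With p adjusted over the list alone, 19 rose and 2 fell. Camera gave an adjusted p = 4.79e-06, and an adjusted p = 0.0796 with an estimated correlation. The Oas1 genes in the list have near-identical copies. Of 16 interferon-inducible GTPase genes 3 rose, also 3 adjusted over the list alone, with a median of 0.12, and camera did not call them (adjusted p = 0.368). Gbp2, whose product attacks vacuoles of intracellular pathogens, had 1.98 ± 0.17. Gbp8 (1.35 ± 0.39) and Gbp3 (0.41 ± 0.12) had edgeR adjusted p of 0.0392 and 0.0406 and lost the call when any library but LPS 2 was left out, with values up to 0.144; 1 member then rose. Gbp genes share reads with close relatives.

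Of 19 tested genes of MHC class I presentation, 7 rose and 2 fell, with a median log2 fold change of 0.33. H2-T22 had 0.79 ± 0.13, and Erap1, which trims peptides for loading, fell with -1.02 ± 0.15. H2-M3 (0.93 ± 0.28, edgeR adjusted p = 0.0488) lost its call when any library but LPS 3 was left out, with values up to 0.140. H2-T23 (0.60 ± 0.16, edgeR adjusted p = 0.0249) lost it without Vehicle 1, Vehicle 3, LPS 1 or LPS 2, with values up to 0.0876. Adjusted over the list alone 9 rose and 3 fell. The number of rises was 11 without LPS 3 and between 1 and 3 without any other library, and 1 member fell without Vehicle 1, Vehicle 2, Vehicle 3 or LPS 2. Camera gave an adjusted p = 0.0206, and 0.295 as the adjusted p with an estimated correlation. Some H2 genes have near-identical copies, and the values of those are uncertain.

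Of 9 tested genes of MHC class II presentation and costimulation, 5 rose and 1 fell. The costimulatory receptor gene Cd40 had 2.21 ± 0.21, Cd83 1.91 ± 0.21 and Cd74, the invariant chain, 1.74 ± 0.13. Ctss, a protease that cleaves the invariant chain, had -0.34 ± 0.10 and lost its call without Vehicle 1, Vehicle 2, Vehicle 3 or LPS 2 (edgeR adjusted p up to 0.107, against 0.0336). When adjusted over the list alone, 5 rose and 2 fell, the median was 0.39, and the camera adjusted p = 0.0505 (0.0332 to 0.113 over the alternatives with the preset correlation).

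The list of the inflammasome and pyroptosis holds Il1b, the cytokine that the inflammasome processes. Il1b rose from 1.78 ± 0.49 to 417 ± 134 CPM (SD, n = 3), a log2 fold change of 7.90 ± 0.37. Casp4, which binds LPS in the cytosol, and the sensor gene Nlrp3 rose with 1.18 ± 0.15 and 0.97 ± 0.12. Nlrp1b had -1.71 ± 0.45 (edgeR adjusted p = 0.0258) and lost its call without any library but Vehicle 3, with values up to 0.0914. Of 15 tested members 4 rose and 1 fell, the same as adjusted over the list alone, with a median of 0.28. The camera test gave an adjusted p = 0.0214, an adjusted p = 0.0594 with a block for the replicate number, and an adjusted p = 0.144 with an estimated correlation. Over the alternatives with the preset correlation it ran from 0.00702 to 0.0594. Naip genes, of which 3 were tested, are near-identical copies.

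Enzymes that make nitric oxide, itaconate and prostaglandins rose. Of 17 tested members 12 rose and 1 fell, with a median log2 fold change of 0.86. Nos2 had 7.67 ± 0.15 (edgeR adjusted p = 1.73e-07). Ptgs2, the inducible cyclooxygenase, had 5.54 ± 0.22, and Acod1, which makes itaconate from an intermediate of the tricarboxylic acid cycle, rose from 347 ± 40.0 to 3469 ± 282 CPM (SD, n = 3). Alox5ap, needed for leukotriene synthesis, fell with -0.67 ± 0.11, and 2 members fell without LPS 3. Adjusted over the list alone 12 rose and 2 fell, and camera gave an adjusted p = 2.95e-06, and an adjusted p = 0.0970 with an estimated correlation.

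Most genes of acute-phase and secreted defence proteins rose. Lcn2 and Saa3 rose with log2 fold changes of 8.53 ± 0.21 and 6.37 ± 0.32, and Slpi, a protease inhibitor, with 3.67 ± 0.31. Of 15 tested members 9 rose and 3 fell, the same as adjusted over the list alone, with a median of 1.67. Camera gave an adjusted p = 0.00511, and an adjusted p = 0.171 with an estimated correlation.

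Among genes of matrix proteases, adhesion and migration, 10 of 24 tested rose and 6 fell. Ccrl2, an atypical chemokine receptor, had 3.63 ± 0.31, and the matrix metalloproteinase genes Mmp13 and Mmp9 had 2.81 ± 0.17 and 2.39 ± 0.20. The integrin gene Itga4 fell with -1.41 ± 0.22. With p adjusted over the list alone, 12 rose and 6 fell. The median was 0.32, or up to 0.57 without 1 library (Vehicle 3), and the camera adjusted p = 0.0545, with 0.00517 to 0.240 over the alternatives with the preset correlation.

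**Figure D2:**
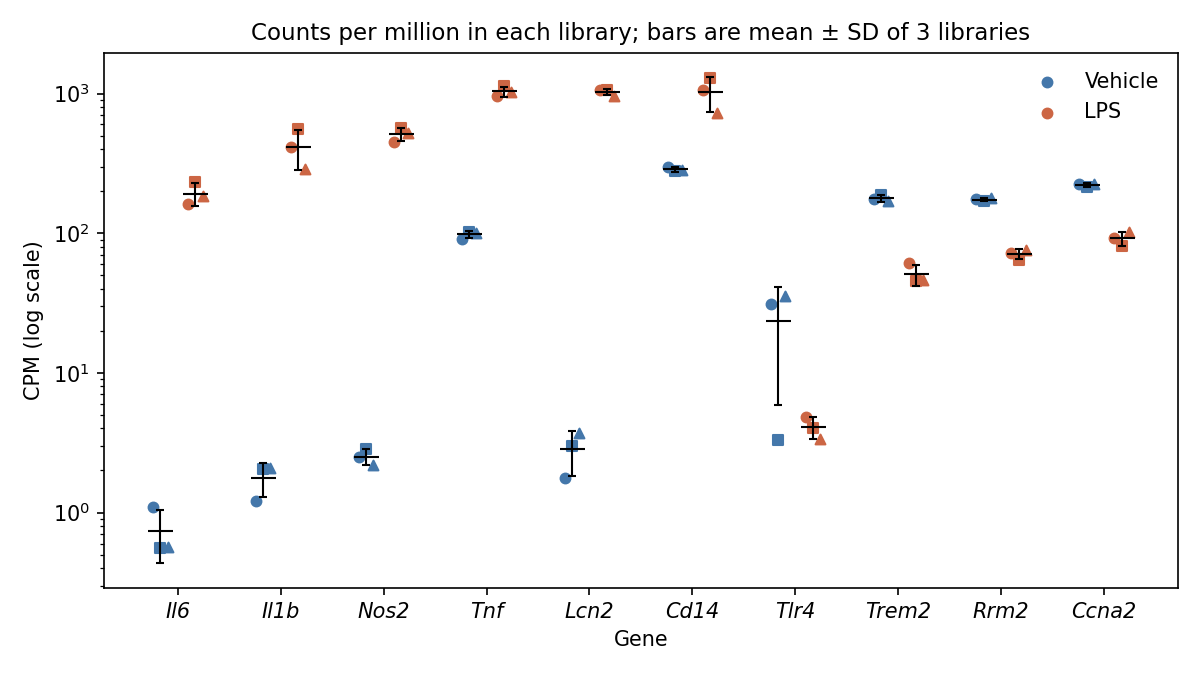
CPM on a log axis of 10 genes in each library; blue marks Vehicle and orange LPS, the symbol shows the replicate number, and the black bars give the mean ± SD of 3 libraries. Il6, Il1b, Nos2, Tnf, Lcn2 and Cd14 lie higher in every LPS library, Trem2, Rrm2 and Ccna2 lower, and for Tlr4 the Vehicle 2 library (3.31 CPM) lies just below the LPS libraries.

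Genes that mark resting microglia fell more often than they rose. Of 18 tested members of the homeostatic list 9 fell and 2 rose, with a median log2 fold change of -1.01. The purinergic receptor gene P2ry13 had -2.53 ± 0.41, from 1.89 CPM in Vehicle. P2ry12 was near the floor, with 0.84 ± 0.13 CPM in Vehicle and 0.12 ± 0.12 in LPS (SD, n = 3). Its edgeR adjusted p = 0.0194 was lost without Vehicle 2, Vehicle 3, LPS 1 or LPS 2, and ran from 0.0168 to 0.105 over all alternatives. Tmem119 did not pass the test, with 2.01 ± 0.16 and 2.08 ± 0.49 CPM (SD, n = 3). Entpd1, an ectonucleotidase, rose with 0.88 ± 0.11. Adjusted over the list alone 12 fell and 3 rose. The number of falls was 5 without Vehicle 2 or LPS 2. The camera test gave an adjusted p = 0.00247, an adjusted p = 0.0773 after a stricter filter on low counts, and an adjusted p = 0.0809 with an estimated correlation.

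Genes linked to disease-associated microglia fell more often than they rose. Of 23 tested members 11 fell and 2 rose, and the median log2 fold change was -0.39. The growth factor gene Igf1 had -1.91 ± 0.14, Trem2, a lipid-sensing receptor, -1.81 ± 0.13, and Lpl, a lipase, -1.66 ± 0.10. Spp1, which encodes osteopontin, rose from 6022 ± 356 to 9398 ± 525 CPM (SD, n = 3). When adjusted over the list alone, 11 fell and 3 rose, and camera gave an adjusted p = 0.00292, and an adjusted p = 0.171 with an estimated correlation.

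Of 13 tested genes of complement and Fc receptors, 2 rose and 2 fell, as they did adjusted over the list alone. C1qb and C1qc, chains of the complement protein C1q, had -2.24 ± 0.32 and -1.96 ± 0.36 from 3.50 and 3.33 CPM in Vehicle. C3ar1 and Fcgr2b had 0.68 ± 0.12 and 0.60 ± 0.11. The median was -0.16 and camera did not call the list (adjusted p = 0.706). Of 13 tested genes of alternative activation and anti-inflammatory signalling, 3 rose and 4 fell, again the same adjusted over the list alone. Il1rn, the antagonist of the interleukin 1 receptor, rose from 51.5 ± 8.14 to 501 ± 36.1 CPM (SD, n = 3). Mrc1, the mannose receptor, fell from 2.42 ± 0.38 to 0.15 ± 0.06, and Ccl24 had 0.59 ± 0.10 CPM in Vehicle and 0.03 ± 0.06 in LPS (SD, n = 3). The call of Ccl24 was lost without Vehicle 2 or LPS 2 (edgeR adjusted p up to 0.0631, against 0.0172). Camera did not call this list (adjusted p = 0.323), and its median of -0.48 and mean of -0.61 were negative where the test fry gave an upward direction (adjusted p = 0.542). The median was -0.30 without Vehicle 2 and -0.27 without LPS 2.

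Transcription factors of macrophages changed in both directions. Of 74 tested members 25 rose and 12 fell, and 29 and 13 adjusted over the list alone. Nr4a1, an early-response nuclear receptor, and Myc had log2 fold changes of 2.35 ± 0.23 and 2.13 ± 0.28. Batf was at 0.03 ± 0.06 CPM in Vehicle and 1.46 ± 0.14 in LPS (SD, n = 3; edgeR adjusted p = 0.00141). The median was 0.19. Camera gave an adjusted p = 0.0138, an adjusted p = 0.0606 after a stricter filter on low counts, and an adjusted p = 0.0809 with an estimated correlation.

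Genes of the cell cycle fell almost throughout. In each of the lists for G2/M and mitosis and for DNA replication, 27 of 30 tested members fell and none rose, and 28 fell adjusted over the list alone. The cyclin gene Ccna2 fell from 221 ± 7.25 to 91.9 ± 10.6 CPM (SD, n = 3), a log2 fold change of -1.26 ± 0.10. Kif11, Nuf2 and Prc1, which act on the mitotic spindle, had -1.36 ± 0.21, -1.35 ± 0.12 and -1.24 ± 0.14. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, had -1.30 ± 0.09, and the DNA polymerase alpha and primase genes Pola1 and Prim1 had -1.30 ± 0.24 and -1.24 ± 0.13. Ccne2 had -1.31 ± 0.30 and lost its call without Vehicle 2, Vehicle 3 or LPS 2 (edgeR adjusted p up to 0.0784, against 0.0191). The G2/M members that did not pass were Mki67, Cenpe and Cenpf (edgeR adjusted p of 0.121, 0.152 and 0.157). For each of them LPS 1 lay more than 3-fold below the other LPS libraries. The median was -1.06 for G2/M and mitosis and -0.82 for DNA replication. The camera test gave an adjusted p = 1.20e-14 for each, and with an estimated correlation an adjusted p = 0.0809 and 0.0796.

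Targets of p53 and genes of cell cycle arrest rose. Of 18 tested members 11 rose and 1 fell, the same adjusted over the list alone, with a median log2 fold change of 0.80. Gadd45a, a stress sensor, had 2.18 ± 0.15, and Bbc3, a promoter of apoptosis, had 1.31 ± 0.20. Fas had 1.54 ± 0.37 and lost its call without Vehicle 1, Vehicle 2 or LPS 2 (edgeR adjusted p up to 0.0760, against 0.0185). Sesn1 fell with -0.64 ± 0.12. Camera gave an adjusted p = 0.00205, and an adjusted p = 0.325 with an estimated correlation.

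In the list of the unfolded protein and integrated stress response 16 of 27 tested members rose and 2 fell, with a median log2 fold change of 0.60. Ddit3, which encodes the transcription factor CHOP, rose from 27.7 ± 0.70 to 128 ± 24.9 CPM (SD, n = 3). Chac1, which degrades glutathione, had 2.01 ± 0.17 and Ppp1r15a, a phosphatase subunit that restores translation, 1.98 ± 0.10. The chaperone gene Canx fell with -0.51 ± 0.08. Adjusted over the list alone 18 rose and 4 fell, and camera gave an adjusted p = 1.16e-05, and an adjusted p = 0.0809 with an estimated correlation. Of 23 NRF2 and antioxidant genes 11 rose and 1 fell, the same adjusted over the list alone, with a median of 0.46. Sqstm1, an autophagy receptor, rose from 498 ± 34.6 to 3308 ± 680 CPM (SD, n = 3), and Slc7a11, which imports cystine, had 2.71 ± 0.12. Nqo1 was at 0.09 ± 0.10 CPM in Vehicle and 1.35 ± 0.32 in LPS (SD, n = 3), and Gclc, which makes the precursor of glutathione, fell with -0.75 ± 0.12, and 2 members fell without LPS 3. The camera test gave an adjusted p = 0.00171, and an adjusted p = 0.155 with an estimated correlation. Of 13 heat shock genes none rose and 2 fell, also adjusted over the list alone, with a median of -0.09, and camera did not call them (adjusted p = 0.552). Hspd1 had -0.51 ± 0.09, and Hspa8 had -0.47 ± 0.10 and lost its call without Vehicle 1 or Vehicle 2 (edgeR adjusted p up to 0.0601, against 0.0125).

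In the list of lysosome and autophagy genes 12 of 31 tested members fell and 6 rose, the same adjusted over the list alone. The cathepsin genes Ctsk and Ctsl fell with log2 fold changes of -1.44 ± 0.13 and -0.77 ± 0.08, and Tfeb, a transcription factor of lysosome genes, with -0.75 ± 0.16. Sqstm1, also in this list, rose with 2.73 ± 0.16. The median was -0.03 and the camera adjusted p = 0.194.

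Genes of energy metabolism went both ways. Of 24 glycolysis genes 9 rose and 3 fell, also adjusted over the list alone, with a median log2 fold change of 0.04 (camera adjusted p = 0.288). The glucose transporter gene Slc2a1 rose from 172 ± 4.77 to 327 ± 30.1 CPM (SD, n = 3), a log2 fold change of 0.93 ± 0.09, and the lactate transporter gene Slc16a1 fell with -0.72 ± 0.09. Pfkfb3 (0.79 ± 0.19) lost its call without Vehicle 3, LPS 1, LPS 2 or LPS 3, and Hk1 (0.76 ± 0.19) without Vehicle 2, Vehicle 3, LPS 2 or LPS 3 (edgeR adjusted p up to 0.0678 and 0.0871, against 0.0194 and 0.0254). The number of rises in glycolysis was 5 without Vehicle 2, Vehicle 3 or LPS 2, and the number of falls 2 without Vehicle 1, Vehicle 2 or LPS 1.

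Of 42 genes of oxidative phosphorylation 2 rose and 5 fell, and 2 and 4 adjusted over the list alone, with a median of -0.00 (camera adjusted p = 0.676). Uqcrq rose with 0.76 ± 0.10, and Sdhd and Ndufs1 fell with -0.54 ± 0.09 and -0.50 ± 0.10. Cox6a1 (0.52 ± 0.14) lost its call without Vehicle 2, Vehicle 3, LPS 1 or LPS 2 (edgeR adjusted p up to 0.0871, against 0.0263). LPS 3 stood apart from the other LPS libraries in this list, with a mean log2 difference from Vehicle of -0.31 against 0.14 in LPS 1 and 0.12 in LPS 2. Without LPS 3, 7 members rose and 4 fell; 1 rose without Vehicle 2, LPS 1 or LPS 2, and 2 or 3 fell without Vehicle 1, Vehicle 2, Vehicle 3 or LPS 2. Of 25 genes of the tricarboxylic acid cycle 3 rose and 4 fell, also adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.531). Pcx, which feeds oxaloacetate into the cycle, had 0.89 ± 0.13, and Idh1 and Idh3a had -0.75 ± 0.10 and -0.58 ± 0.10. A single member rose without Vehicle 1, Vehicle 3, LPS 1 or LPS 2.

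Of 22 tested genes of cholesterol synthesis and uptake 6 fell and 1 rose, with a median log2 fold change of -0.20. Ebp, Insig1 and Idi1 had -0.63 ± 0.13, -0.60 ± 0.11 and -0.52 ± 0.11, and Mvd rose with 0.52 ± 0.11. With p adjusted over the list alone, 8 fell and 1 rose. Camera gave an adjusted p = 0.0335, an adjusted p of 0.0572, 0.0517 and 0.0741 without Vehicle 1, Vehicle 3 and LPS 3, an adjusted p = 0.0538 with a block for the replicate number, and an adjusted p = 0.151 with an estimated correlation. Over the alternatives with the preset correlation it ran from 0.0186 to 0.0741. Without LPS 3, 2 members rose. Of 17 genes of cholesterol efflux and LXR targets 8 fell and 1 rose, and 10 and 4 adjusted over the list alone, with a median of -0.36. Mylip, which triggers breakdown of the LDL receptor, had -0.89 ± 0.13 and the apolipoprotein gene Apoe -0.61 ± 0.09, while Npc1, a lysosomal cholesterol transporter, rose with 0.52 ± 0.09. Nr1h3 (-0.66 ± 0.18), which encodes LXR alpha, lost its call when any library but LPS 3 was left out (edgeR adjusted p up to 0.0875, against 0.0295). The number of falls in this list was 5 without Vehicle 1, Vehicle 3, LPS 1 or LPS 2, and the number of rises was 2 without Vehicle 3 and 3 without LPS 3. For this list camera gave an adjusted p = 0.0124, and an adjusted p = 0.117 with an estimated correlation.

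**Figure D3:**
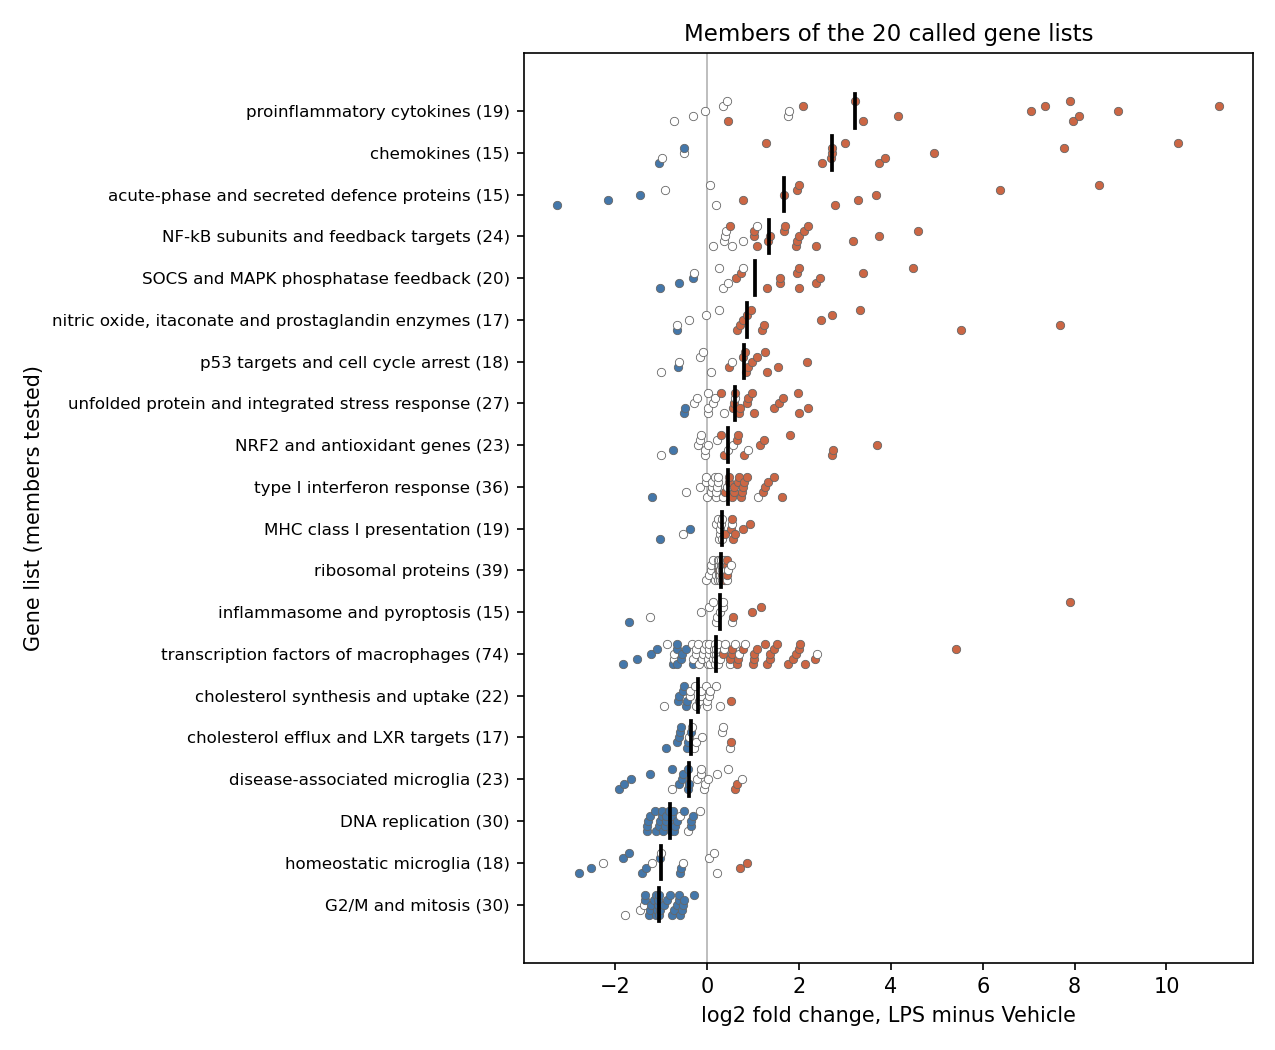
Fitted log2 fold changes (LPS minus Vehicle) of every tested member of the 20 called gene lists; filled points passed edgeR's test (orange higher, blue lower), open points did not, and black lines are list medians. Medians run from 3.22 for proinflammatory cytokines to -1.06 for G2/M and mitosis; the fitted values of Il12b, Tnfsf15 and Cxcl3, at 0 in Vehicle, depend on the fit and measure no exact fold.

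Ribosomal protein genes differed between the LPS libraries. Their mean log2 difference from Vehicle was 0.40 in LPS 1, 0.47 in LPS 2 and -0.05 in LPS 3. Of 39 tested members 8 rose, none fell and the median log2 fold change was 0.30, and 5 rose adjusted over the list alone. Rplp1 had 0.44 ± 0.07, and Rps20 (0.43 ± 0.13, edgeR adjusted p = 0.0451) lost its call when any library but LPS 3 was left out, with values up to 0.171. The number of rises was 34 without LPS 3 and between 1 and 3 without any other library. The camera test gave an adjusted p = 0.000328, and an adjusted p = 0.582 with an estimated correlation. Fry did not call the list (adjusted p = 0.144). Lists of genes matched on transcript length and level had median log2 fold changes of -0.02 to 0.27, centred on 0.14. Part of the median of 0.30 was thus shared by genes of like length and level.

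Of 8 tested astrocyte markers 1 rose, the glycolytic gene Aldoc with 0.53 ± 0.10, of 9 neuron markers 1 rose, Syn1, and none of 5 oligodendrocyte markers changed. Each count was the same adjusted over the list alone, and camera called none of these lists (adjusted p of 0.984, 0.676 and 0.846). The median log2 fold changes were -0.42, -0.24 and 0.04, and for astrocyte markers fry gave an upward direction (adjusted p = 0.913). LPS 1 had the lowest mean of each, with log2 differences from Vehicle of -1.83, -3.01 and -1.70. Only 3 fibroblast and endothelial markers and 2 lymphocyte markers were high enough to be tested, and none passed; adjusted over the list alone, 1 lymphocyte marker was lower, Cd4, which was singled out after its values were seen. The 37 genes encoded on the mitochondrial genome were listed at 0 in every library and could not be tested.

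Of the 34 lists tested camera called 20, 14 higher and 6 lower, at an adjusted p under 0.05 with a preset correlation of 0.01. With an estimated correlation it called 0, although 24 lists moved on balance in 1 direction and 30 changed in either direction by fry's tests at an adjusted p under 0.05. Fry does not compare a list with other genes.

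In lists that camera did not call, the median log2 fold change also moved with single libraries. It ran from -0.06 (without LPS 3) to 0.12 (without Vehicle 3) for the TLR4 receptor and adaptors, and from -0.01 (without LPS 3) to 0.26 (without LPS 1) for interferon-inducible GTPases. For glycolysis it ran from -0.03 (without LPS 2) to 0.06 (without LPS 3), for oxidative phosphorylation from -0.09 (without LPS 1) to 0.14 (without LPS 3), and for the tricarboxylic acid cycle from -0.13 (without LPS 2) to -0.00 (without LPS 3). Complement and Fc receptors had -0.17 (without Vehicle 2) to -0.05 (without LPS 1), lysosome and autophagy -0.10 (without LPS 1) to -0.03 (without Vehicle 1), and heat shock genes -0.14 (without Vehicle 3) to -0.02 (without LPS 1). Astrocyte markers had -0.76 (without LPS 2) to 0.06 (without Vehicle 2), neuron markers -0.80 (without LPS 2) to 0.21 (without LPS 1), and oligodendrocyte markers -0.23 (without LPS 3) to 0.09 (without Vehicle 3).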

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

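Division of the values by their step was the only alternative chosen after seeing the data. The number of changed genes was 3844 with the size factors of DESeq2, 3849 with upper-quartile factors, 3908 with total counts only, 3540 without a filter, 3467 with a stricter filter, 4494 with the DESeq2 Wald test, 3690 with limma voom, 3550 with edgeR's test before version 4 and 3834 after division by the step. These stayed within 1.5 times the reported 3864, and no gene was called with the opposite sign in any of them or without a library. Genes changed at least 2-fold numbered 732 with the stricter filter, which tested 10537 genes in place of 16371.

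Leaving out a library gave 2344 (without Vehicle 2) to 4535 (without LPS 3) changed genes, 1291 to 2450 higher, 1053 to 2085 lower and 969 to 1356 changed at least 2-fold. Fewer libraries leave less power, but why the number rose without LPS 3 was not tested here. A block for the replicate number gave 3816 changed genes and kept 89.3% of the calls. The deviations of libraries with the same number correlated across genes with r of 0.07, 0.05 and 0.06. Libraries with different numbers had lower r, from -0.06 to 0.01. All these values are small, and whether the numbers pair the libraries cannot be told from them.

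With an estimated correlation camera called 0 lists, against 20 with the preset one. Some lists that lost the call had an estimated correlation below the preset 0.01. It was -0.0337 for SOCS and MAPK phosphatase feedback and -0.00417 for the type I interferon response. For such lists a higher correlation between genes cannot be the cause. Other lists lay above 0.01, up to 0.746 for ribosomal proteins. G2/M and mitosis, at 0.118, had a camera adjusted p = 0.0809 with the estimated correlation. Both lists named above had 0.0796. An adjusted p with an estimated correlation thus cannot be read as a measure of the correlation in a list alone. The cause of the lost calls was not tested further. With the preset correlation it called 18 (replicate block, which lost the inflammasome and cholesterol synthesis lists) to 22. For the sample structure, the first component held 33.6% of the variance without a filter and 61.6% with the stricter filter. Some genes and lists near the floor were not tested under the stricter filter and have no value there. Among values of named genes under an alternative, 2005 kept their direction and side of the threshold, 95 lost the call, 2, both of Tlr4, gained it and 3 turned sign. All 3 were of Tmem119, which was called in no setting. Its log2 fold change turned to -0.0384 with total counts only, -0.0122 without Vehicle 1 and -0.168 without LPS 1, and the highest value with 1 library left out was 0.146, without LPS 3. For lists these numbers were 445, 27, 15 and 19.

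The 19 list medians that turned sign were not called before or after. Here medians are of differences in log2 CPM. With all libraries they were -0.0225 for the TLR4 receptor and adaptors, 0.0652 for interferon-inducible GTPases, -0.155 for complement and Fc receptors, -0.472 for alternative activation and anti-inflammatory genes, 0.0345 for glycolysis, -0.0296 for oxidative phosphorylation and -0.0360 for the tricarboxylic acid cycle. Astrocyte, neuron and oligodendrocyte markers had -0.538, -0.706 and -0.300. The fitted medians were 0.01 for the TLR4 receptor and adaptors and 0.04 for oligodendrocyte markers, so the sign of both depended on the measure, and -0.24 for neuron markers. With total counts only they were -0.0226 for interferon-inducible GTPases and -0.0537 for glycolysis. Without a filter the TLR4 receptor and adaptors had 0.0143. With the stricter filter interferon-inducible GTPases had -0.0165, complement and Fc receptors 0.0461, and alternative activation and anti-inflammatory genes 0.0510. After division by the step interferon-inducible GTPases had -0.00468. With 1 library left out the lists ran as follows. The TLR4 receptor and adaptors had -0.0510 (without LPS 3) to 0.0783 (without Vehicle 3), and interferon-inducible GTPases -0.0453 (without LPS 3) to 0.264 (without LPS 1). Glycolysis had -0.0291 (without LPS 2) to 0.0588 (without LPS 3), oxidative phosphorylation -0.130 (without LPS 1) to 0.131 (without LPS 3), and the tricarboxylic acid cycle -0.127 (without LPS 2) to 0.00803 (without LPS 3). Astrocyte markers had -0.973 (without LPS 2) to 0.182 (without LPS 1), neuron markers -1.46 to 0.275 and oligodendrocyte markers -0.680 to 0.0796, without the same libraries.

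Low counts, and the step of about 3.75, limit what can be said of genes near the floor such as P2ry12, Ccl24 and Batf.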

Other observations

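The gene families of the first paragraph, and the tests of a weaker response and of scaling, were chosen only after the results were seen. Genes for cytosolic aminoacyl-tRNA synthetases, which charge transfer RNA for translation, rose in 11 of 20 tested cases with none lower (median log2 fold change 0.36). Of the 17 mitochondrial ones 1 rose and 3 fell. Genes of homologous recombination and the Fanconi anaemia pathway, which repair DNA, fell in 15 of 26 cases with a median of -0.78, and centromere proteins in 10 of 21 with -0.73; none rose in either. Cenpa, Cenpe and Cenpf are also in the G2/M list. Of 17 TNF receptor superfamily genes 8 rose and 1 fell (median 0.44). Of 20 amino acid transporters 5 rose and 1 fell, of 24 growth factor and cytokine receptors 4 rose and 5 fell, and of 9 Toll-like receptors 2 rose and 3 fell. No p of a set test is given for these 8 families, because the families were chosen with the results in view.

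The real grouping gave 3864 changed genes and the highest of the other splits gave 1. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one, and 10 splits are too few for a share under 0.05. Every other split puts both treatments in each of its groups. A difference by treatment then adds to the spread within groups, so few calls were bound to follow there. The splits therefore cannot decide whether the grouping arose by chance.

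Replication and mitosis genes fell with LPS. Over 4 scalings their median log2 fold change ran from -0.998 to -0.911. The TMM factors lay between 0.944 and 1.04, so these scalings were too alike to bring that median near 0. A scaling moves all genes of a library alike, and the median of all tested genes was -0.02. Scaling therefore cannot make these genes fall relative to the others. The amount of RNA per cell was not measured. Length of the longest annotated transcript was argued against as the whole cause, since lists matched on it and on level had medians of -0.11 to 0.13 against -0.91. LPS treatment is a candidate explanation that stays open, as do technical differences between the groups that were not tested.

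Ribosomal protein genes were lower in LPS 3 than in LPS 1 and LPS 2, by a median log2 difference of -0.50. Across genes, the difference of LPS 3 from its group mates went with length (Spearman's rho of 0.33). For LPS 1 and LPS 2 rho was -0.21 and -0.23, but LPS 3 is among their mates, so these values are not separate from it. For Vehicle libraries rho lay between -0.06 and 0.08. Lists matched on length and level reached -0.32 to -0.06, which argues against length, as annotated, as the whole cause. The match was imperfect, with a median length of 1151 against 1352 and 712 against 456 CPM. Expressed transcripts can be shorter than the longest annotated one used here, so their length stays open as a cause. A weaker response in LPS 3 was argued against as the whole cause. The comparison used 1348 other genes, called and changed at least 2-fold with LPS 3 left out. They kept a median of 0.825 of their change in LPS 3. Ribosomal protein genes, with a median log2 change of 0.44 in LPS 1 and LPS 2, were not chosen by such a cut. They fell short of that share by a median of -0.42, while the list means of libraries of the same group, LPS 3 aside, lay at most 0.0759 apart. The members move together (estimated correlation 0.746), so no interval over members is given. This test replaced one on the ratio alone, which lay too close to its bound to decide. Other explanations were not tested and stay open.

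In 145 of 10790 genes with a mean of at least 5 CPM, a library lay under its group mates by more than 3-fold, 158 drops in all, as for Tlr4 in Vehicle 2. Libraries drawn with Poisson noise held 0 drops on average over 20 sets, and the most in any set was 0. Against 158 drops, this argues against counting error of reads as the cause of the drops as a set. The draws cover counting error only and take reads as independent molecules. Other sources of noise between single libraries cannot be told apart by them. Genes with a drop overlapped an expressed gene in 47.2% of cases against 34.0% of matched genes (Fisher's exact test, two-sided, p = 0.00241). Yet only 53.2% of the overlapping genes (59 of 111, 95% interval 43.4% to 62.7%) lay above their mates in that library, so reads assigned to an overlapping gene cannot be told apart from other sources. No biological explanation was tested.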
